A study of Mus musculus with 8 samples.

How the data were processed

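Bulk RNA sequencing libraries from the aortas of male mice carrying the Fbn1 C1041G allele on a single chromosome were compared between 4 mice aged 12 weeks and 4 aged 2 years. The deposited tables give raw counts per gene, per the labels and the file headers, with 25526 gene symbols listed in each library and no identifiers beside the symbols. Per the labels' protocols, RNA was isolated as total RNA with a column kit and sequenced on a NovaSeq instrument. The submitters' processing notes name the mouse genome build GRCm39. The aligner, the counting tool, the gene annotation, the handling of strand and of reads that match several genes, and the selection of mRNA during library preparation are not given in the sources used here. Counts of gene families with near-identical members, and of genes that overlap on opposite strands, are therefore uncertain. The count values were whole numbers in every table and every library summed to a different total.

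All 8 libraries were assigned to age groups from their labels. Library totals ranged from 16251986 to 33880690 counts. Of the listed genes, 8096 had 0 counts in all libraries, and 13978 passed edgeR's expression filter (filterByExpr with its defaults) and were tested. Scaling factors were computed by the trimmed mean of M values (TMM). Genes were tested with edgeR's quasi-likelihood F test, with robust dispersion estimation and age as the model's only term, and p-values were adjusted by the Benjamini-Hochberg method over all genes tested. A gene was called changed at an adjusted p below 0.05. Log2 fold changes are 2 years over 12 weeks, so positive values are higher at 2 years, and their standard errors (SE) were derived from the fold change and the F statistic. CPM, counts scaled to a library size of 1e6, use the TMM-scaled library sizes, and logarithms of CPM use a prior count of 2. A fold change against a group in which all libraries had 0 counts is given as a lower bound against a floor of 3 counts over the group. Such a floor covers counting error only. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0.

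Before the data were examined, 35 gene lists were fixed: contractile and modulated smooth muscle, matrix groups, signalling, cell cycle, senescence, immune groups, stress, metabolism, imprinted growth genes, the circadian clock and markers of other cell types that a dissected aorta can hold. The 34 lists with at least 5 tested members were compared with all other genes by limma's camera test on voom values with a preset correlation between genes of 0.01. The Benjamini-Hochberg adjustment ran over those lists. Camera with an estimated correlation and limma's fry test were alternatives. For each list the members called over all genes tested are given, and the number called when p-values were adjusted over the list alone is given where it differs. Some genes stand in more than 1 list, among them Spp1, Ctss, Timp1, Mmp3, Ly6a and C1qa.

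The rule for genes named in the text was also fixed before the data were examined. It takes Fbn1; the 10 genes with the largest fold change in each direction among called genes with a mean of at least 1 CPM, no overlap between the groups and a symbol that is not a predicted or clone name; for each list up to 4 called members with the smallest p, or up to 2 members with the highest mean CPM where none was called; and Eln, Col1a1, Col3a1, Acta2, Myh11, Tgfb2, Mki67 and Cdkn2a whatever their result. The genes named under other observations stand outside this rule and were chosen after their values were seen; the male genes are library checks. Some genes that the rule takes are not reported here.

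Transcript length, GC share and intron length were taken by symbol from the GENCODE M21 annotation, which belongs to the older build GRCm38, using the longest protein-coding transcript of each gene. A length and GC share were found for 13847 of the tested genes (99.1%). No coordinates are given because the builds differ. An offset that removes a per-library trend on length and GC (natural splines with 4 degrees of freedom each) was added as an alternative after the fold changes had been seen to depend on length. The length slope of a library is the slope of its log2 CPM, relative to each gene's mean over all libraries, on log2 transcript length.

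Differences in library measures were tested with exact permutation tests over the 70 assignments of 8 libraries to groups of 4, two-sided, for which the smallest possible p is 0.0286. Spread within a group was measured as the root mean square distance, in log2 CPM, of each library from the mean of the other 3 libraries of its group. Pairs of libraries within a group differed by 23.5 to 150.5 times the variance expected from counting alone (chi-square per degree of freedom), so no library was counted as a copy of another. The pipeline was tested on counts simulated from the 2-year against 12-week comparison over 13892 genes. Of genes changed 2-fold 68% were recovered, and of genes changed 1.5-fold 9%, with 4 false calls among 81. Only a small part of the simulated genes was changed, while 52.0% of genes were called in the data. These shares therefore do not give the power of the real test. When a length trend was added to the simulated 2-year counts, 663 false calls arose without the offset (13880 genes) and 6 with it (13751 genes). That trend had a form which the offset can remove by construction, so the result does not show how well the offset suits the data.

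Alternatives planned before the data were examined were relative log expression and upper-quartile factors, no filter beyond 1 count in total, a filter of at least 1 CPM in 4 libraries, DESeq2, limma voom with and without sample weights, a block on replicate number, 1 surrogate variable, leaving out each library, scaling factors without the adipocyte, muscle, nerve and red blood cell genes, and a threshold of 0.01. The length and GC offset, with and without the block, and the removal of 2 libraries together (12 weeks replicate 3 and 2 years replicate 3) were added after seeing the data. The file headers number the libraries 13 to 16 at 12 weeks and 24, 25, 27 and 28 at 2 years, all on lane 1. Any batch that followed this numbering and the age of the mice cannot be told apart. Aortas of mice without the Fbn1 allele were not analysed here.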

Results

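The series asked how the aorta of Marfan mice differs between an age at which aneurysms enlarge and an advanced age at which their growth had stopped. The mice were males heterozygous for Fbn1 C1041G, a missense change in fibrillin-1 that is widely used as a mouse model of Marfan syndrome. Gene expression in aortic tissue was measured by bulk RNA sequencing in 4 mice at 12 weeks and 4 mice at 2 years. Total counts in 12 weeks replicates 1 to 4 were 23622803, 27417541, 26271758 and 24448238. Those in 2 years replicates 1 to 4 were 33880690, 22213413, 16251986 and 28460128. The male genes Ddx3y, Uty, Eif2s3y and Kdm5d had counts in all 8 libraries, as the stated sex requires.

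Fbn1, the mutated gene, was counted in every library. Its level was 761.7, 917.8, 773.9 and 836.3 CPM in 12 weeks replicates 1 to 4 and 512.7, 365.1, 446.9 and 610 CPM in 2 years replicates 1 to 4. The mean fell from 822 ± 71.5 to 484 ± 104 CPM (SD, n = 4), a log2 fold change of -0.77 (SE 0.17, edgeR adjusted p = 0.00309). The Fbn1 transcript is 11971 nt long, and with the length and GC offset its log2 fold change was 0.15 (adjusted p = 0.334, and 2.89e-05 to 0.386 over all alternatives).

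Expression differed widely between the ages. Of 13978 genes tested, 3611 were higher and 3661 lower at 2 years, together 52.0%, and 1640 were higher and 1487 lower by at least 2-fold (edgeR, adjusted p below 0.05). The first principal component held 70.9% of the variance and separated the age groups. Correlations of log2 CPM were 0.970 to 0.985 between 12-week libraries, 0.957 to 0.982 between 2-year libraries and 0.863 to 0.908 across ages. Without 12 weeks replicate 3 and 2 years replicate 3, which stand apart in heart muscle transcripts and in mitochondrial share, 6499 genes were called and 6067 of these were among the 7272 called with all libraries.

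The genes with the largest increases at 2 years included Jchain, Mzb1, Gzmk, Cxcl13 and Slpi. Jchain, the joining chain of secreted antibodies, rose from 0.163 ± 0.0702 to 570.2 ± 406 CPM (log2 fold change 11.76, SE 0.79, edgeR adjusted p = 5.89e-06). Mzb1, a chaperone of antibody-secreting cells, had 0 counts in all 12-week libraries and 2040 counts at 2 years (18.59 ± 16.1 CPM, highest in replicate 4 at 40.62 CPM), at least 666-fold higher. Gzmk, a T cell granzyme, likewise had 0 counts at 12 weeks and was at least 104-fold higher at 2 years, at 3.351 ± 1.49 CPM. Cxcl13, a chemokine that attracts B cells, rose from 0.402 ± 0.175 to 41.0 ± 8.06 CPM (99.7-fold, adjusted p = 2.03e-07). The protease inhibitor Slpi rose from 0.424 ± 0.145 to 51.71 ± 15 CPM (122-fold, adjusted p = 2.03e-07). The others were Saa3 (log2 fold change 9.69), Ly6c2 (7.44), Lcn2 (6.80), Ms4a4c (6.73) and Sirpb1c (6.57), all with an adjusted p of at most 0.00159. Saa3, Ly6c2, Ms4a4c and Sirpb1c have near-identical relatives, so their counts are uncertain. With the length and GC offset Ly6c2 was at 6.65, Slpi at 6.16, Lcn2 at 5.92 and Cxcl13 at 5.91. Leaving out a single library moved some of these by over 1.5-fold: Saa3 to 8.89 without 2 years replicate 3 and 10.97 without 12 weeks replicate 2, Lcn2 to 5.96 without 2 years replicate 3, Ly6c2 to 6.52 without 2 years replicate 4, and the bound for Mzb1 to at least 395-fold without 2 years replicate 4.

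The largest decreases included those of Leng8, Npas4, Cd46 and Ttn. Leng8 fell from 373.6 ± 107 to 13.6 ± 6.52 CPM (27.6-fold, edgeR adjusted p = 6.46e-06) and was by far the most abundant of these. Npas4, an activity-induced transcription factor, fell from 15.1 ± 6.77 to 0.181 ± 0.201 CPM (92.1-fold, adjusted p = 1.41e-05). Cd46 fell from 6.64 ± 1.16 to 0.124 ± 0.0631 CPM (50.5-fold), and Adam1a from 8.89 ± 0.677 to 0.295 ± 0.136 CPM (28.7-fold). Col7a1, Muc2, Muc4, Lgals4 and Rgs11 fell, with log2 fold changes of -5.44, -5.38, -5.10, -4.82 and -4.59, from 12-week means of 2.31 to 4.96 CPM. Adam1a has a close relative in the genome and its counts are uncertain. Titin (Ttn) was also in this group (log2 fold change -6.26, adjusted p = 0.0102), but its 12-week level of 50.35 ± 61.7 CPM varied widely between libraries, and limma voom did not call it (adjusted p = 0.0533). The Ttn transcript is 106824 nt long; its log2 fold change was -3.001 with the length and GC offset, and -2.48 and not called with the offset and the replicate block. Col7a1 and Muc4 were at -4.47 and -4.33 with the offset. Without 12 weeks replicate 3 the value for Ttn was -5.03 and without 2 years replicate 1 it was -7.05; Col7a1 moved to -6.03 without 2 years replicate 1, and Npas4, Muc4 and Rgs11 moved to -7.15, -6.39 and -5.45 without 2 years replicate 3.

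Fold changes depended on transcript length. In 10 bins of genes by length, the median log2 fold change fell from 0.61 at a median length of 1026 nt to -0.64 at 8270 nt, and across genes the Spearman correlation was -0.42 with length and 0.04 with GC share (genes are not independent replicates). In 4 groups of genes by GC share the correlation with length lay between -0.442 and -0.365. The slopes of the deepest and the shallowest library, both at 2 years, differed by 0.349 of the difference between the age groups. All 4 12-week libraries lay between them in depth. Yet the lowest length slope at 12 weeks was 0.1258 and the highest at 2 years was -0.1075. By limits set before it was computed, the ratio of 0.349 left depth undecided. Slopes without overlap at bracketed depths were weighed outside those limits. They argue against depth as the source of the difference between the ages. The length slopes of the libraries were 0.215 ± 0.0608 at 12 weeks and -0.215 ± 0.104 at 2 years (SD, n = 4; exact permutation p = 0.0286, the smallest possible). Ribosomal protein genes, which are short, took 1.82 ± 0.13% of counts at 12 weeks and 4.44 ± 0.872% at 2 years (exact permutation p = 0.0286), and all 79 tested were higher. Their median log2 fold change was 1.34, or 0.45 with the length and GC offset. Named genes that the offset moved by over 1.5-fold are given also with it.

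**Figure D1:**
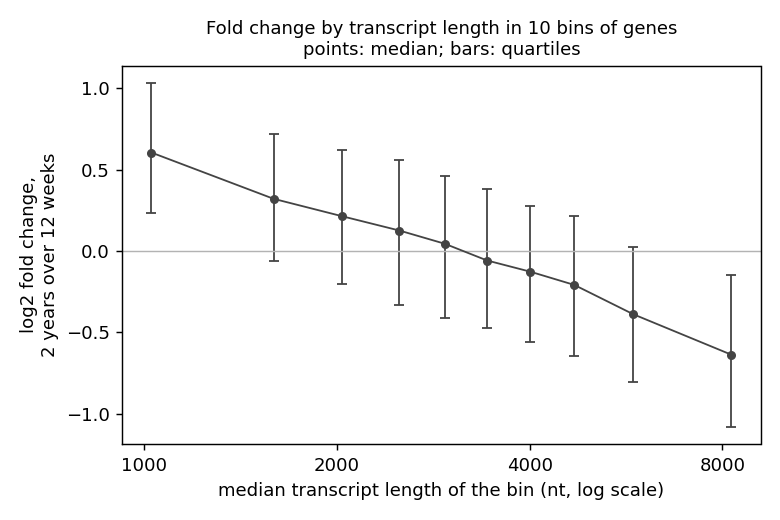
Median log2 fold change (2 years over 12 weeks, vertical axis) of genes in 10 bins by transcript length (horizontal axis, nt, log scale), with bars from the lower to the upper quartile. The median falls from 0.605 in the bin of shortest transcripts to -0.637 in the bin of longest.

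Immune genes rose together at 2 years. Of 20 macrophage genes tested, 17 rose and 0 fell, with a median log2 fold change of 2.36. Cd68 rose from 18.4 ± 1.66 to 76.7 ± 2.81 CPM (4.18-fold, edgeR adjusted p = 6.65e-07), Itgam 5.16-fold, and Adgre1 and C1qa 6.07-fold each. All 16 tested T and NK cell genes rose (median 3.32, and 2.59 with the length and GC offset). Among them were Nkg7, from 0.162 ± 0.0927 to 5.91 ± 0.973 CPM, Cd2 (15.7-fold) and Cd3g (9.84-fold). All 11 tested B and plasma cell genes rose (median 3.86, the same with Mzb1 at its bound), including Cd79b (23.8-fold) and Blk (8.13-fold). Apart from Jchain the lymphocyte genes named here had means below 20 CPM at 2 years. The 12 antibody and T cell receptor constant segments were listed at 0 in all libraries, those with abundant Jchain included, and these values are not read as absent expression. Of 4 neutrophil genes tested 3 rose, including Csf3r (3.88-fold) and S100a8 (31.8-fold), too few for a list test. With 12 weeks replicate 1 or 3 or 2 years replicate 4 left out, 7 were tested and 5 rose, without 12 weeks replicate 2, 5 of 6 rose, and without 12 weeks replicate 4, 6 of 7 rose. In the alternatives with at least 5 members tested, the neutrophil list was called higher without 12 weeks replicate 4 (adjusted p = 0.0481), without 2 years replicate 4 (0.00328) and with no low-count filter (0.022), and its adjusted p ranged from 0.00328 to 0.131. With the length and GC offset the log2 fold changes of Cd68, Nkg7, Cd2, Cd3g and S100a8 went from 2.06, 5.17, 3.97, 3.30 and 4.99 to 1.45, 4.39, 3.30, 2.48 and 3.71. Against all other genes the lists were higher by camera for macrophages (adjusted p = 8.81e-10; adjusted p = 0.418 with an estimated correlation), T and NK cells (1.74e-07; adjusted p = 0.394 with an estimated correlation) and B and plasma cells (0.000105; adjusted p = 0.531 with an estimated correlation).

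Interferon, antigen presentation and complement genes moved in the same direction. Of 22 interferon response genes 20 rose and 0 fell, with Irf7 at 6.17 ± 2.39 against 104 ± 24.3 CPM (16.8-fold, edgeR adjusted p = 1.82e-06), Usp18 up 11.6-fold and Bst2 up 4.33-fold (log2 fold change 2.12, and 1.32 with the length and GC offset). Of 19 antigen presentation genes 18 rose, including the class II gene H2-Eb1 from 70.04 ± 14 to 810.6 ± 150 CPM (11.6-fold), the class I gene H2-K1 (4.11-fold) and the immunoproteasome subunit Psmb8 (7.6-fold). Class I genes resemble one another closely and their counts are uncertain. Of 20 complement genes 12 rose and 1 fell, with the receptors C5ar1 (4.61-fold) and C3ar1 (5.35-fold) among those with the smallest p. Macrophages also express both receptors, C1qa, C1qb and C1qc stand in the complement and the macrophage list, and 17 of 20 macrophage genes rose in the same comparison. Camera placed all of these lists higher: interferon response (adjusted p = 1.76e-08; adjusted p = 0.516 with an estimated correlation), antigen presentation (6.15e-12; adjusted p = 0.0781 with an estimated correlation) and complement (8.93e-05; adjusted p = 0.418 with an estimated correlation). All 8 red blood cell genes tested also rose (camera adjusted p = 0.00184; adjusted p = 0.534 with an estimated correlation). Haemoglobin transcripts took 0.0579 ± 0.0162% of counts at 12 weeks and 0.367 ± 0.306% at 2 years (exact permutation p = 0.0286). Hbb-bs rose 7.36-fold, a log2 fold change of 2.88 that was 2.15 without 2 years replicate 2 and 1.81 with the length and GC offset. Red blood cell transcripts are short (median 991.5 nt), and with the offset 7 rose and the median went from 2.47 to 1.70.

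**Figure D2:**
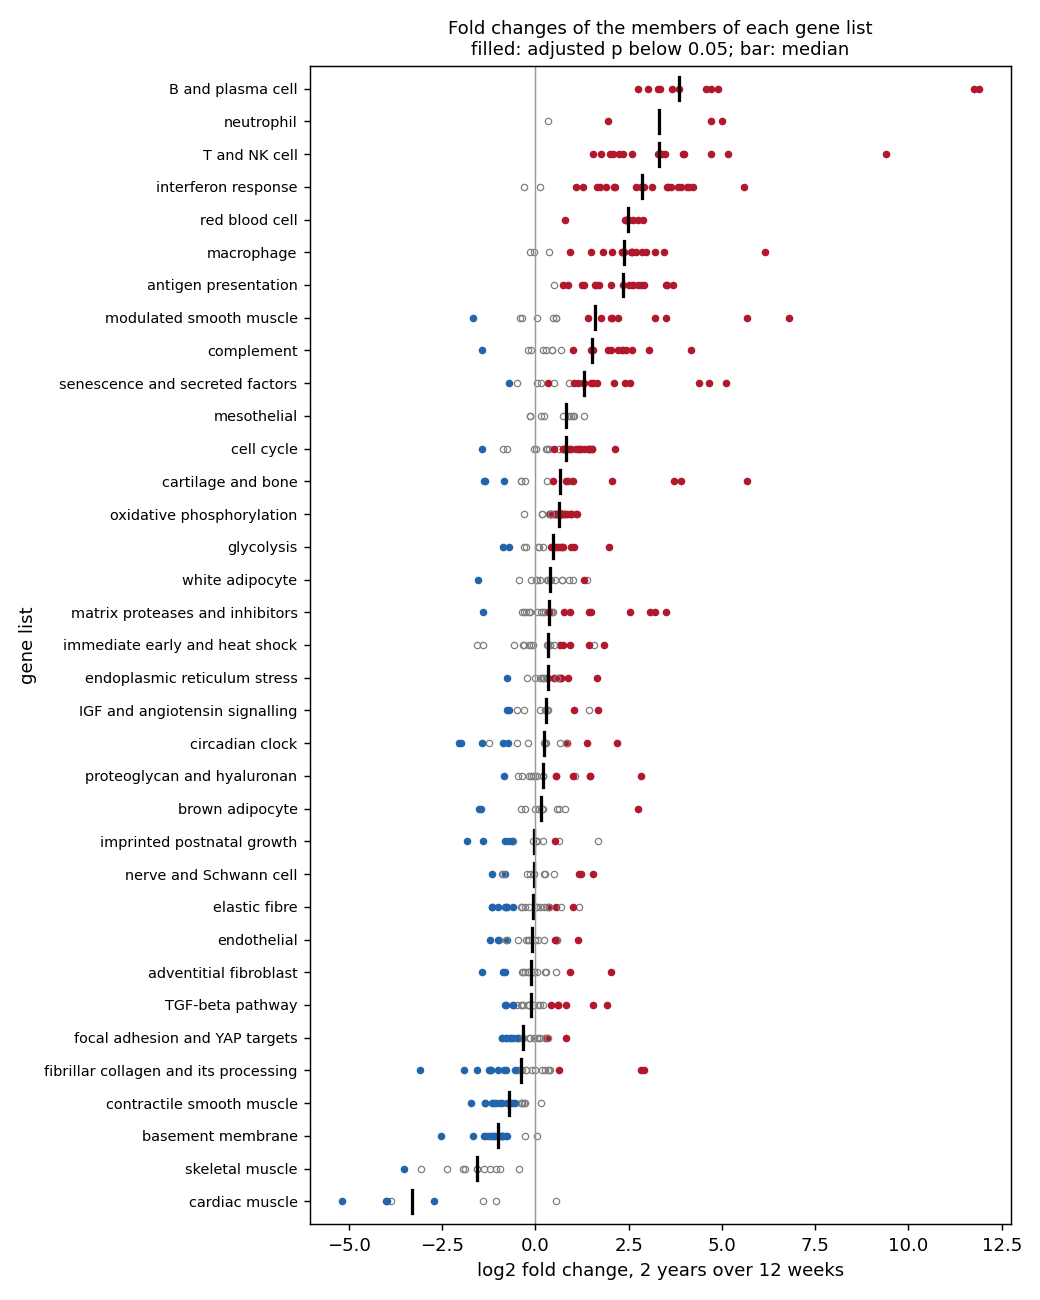
Log2 fold changes (2 years over 12 weeks, horizontal axis) of the tested members of 35 gene lists (vertical axis, ordered by median), with filled points for genes with an adjusted p below 0.05 and a bar at each median. Immune lists lie at the top with medians up to 3.86, and basement membrane (median -1.01) and contractile smooth muscle (median -0.71) lie near the bottom with all called members lower.

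Contractile genes of smooth muscle fell. Of 20 tested, 14 fell and 0 rose (15 fell when adjusted over the list alone), with a median log2 fold change of -0.71 (camera adjusted p = 0.000119; adjusted p = 0.531 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, fell from 7962 ± 1140 to 2416 ± 916 CPM (3.3-fold, edgeR adjusted p = 0.000363). Smtn (smoothelin) fell from 1828 ± 142 to 719 ± 167 CPM, Mylk 2.15-fold (log2 fold change -1.10, and -0.50 with the length and GC offset) and Tpm1 1.85-fold. Acta2 did not pass the threshold (13790 ± 1080 and 10560 ± 2520 CPM, log2 fold change -0.38, adjusted p = 0.144), and was lowest in 2 years replicate 3 at 7120 CPM. With the length and GC offset 15 contractile genes fell, Acta2 among them (-0.75). Bulk counts do not separate a smaller share of smooth muscle RNA from lower expression per cell, and immune genes rose in the same libraries. Of 16 genes of modulated smooth muscle, 9 rose and 1 fell (median 1.59, camera adjusted p = 0.00148; adjusted p = 0.418 with an estimated correlation). Vcam1 rose from 176 ± 45.6 to 809 ± 225 CPM (4.61-fold), Lgals3 4.14-fold and the protease Ctss 11.4-fold (3.51, and 2.86 with the offset). Macrophages also express Lgals3 and Ctss, and macrophage genes rose in the same libraries.

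Matrix genes moved in different directions by group. Of 19 basement membrane genes, 16 fell and 0 rose (17 fell when adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 1.34e-06; adjusted p = 0.47 with an estimated correlation). The laminin chain Lama5 fell from 424 ± 109 to 73.5 ± 22.3 CPM (5.76-fold, edgeR adjusted p = 1.37e-05), Col4a5 fell 3.16-fold, Col6a3 2.42-fold and Lama4 2.19-fold. These transcripts are long (median 6450 nt), and with the length and GC offset 12 fell and 1 rose. Lama5 went from -2.53 to -1.42 with it and Col6a3 from -1.27 to -0.44. Of 26 fibrillar collagen and processing genes, 10 fell and 3 rose, with no call for the list (camera adjusted p = 0.121); with the offset 9 fell and 5 rose, and without 12 weeks replicate 1, 8 fell and 6 rose. Col5a1 and Col5a2 fell 2.27-fold and 2.35-fold, the procollagen protease Bmp1 fell 2.95-fold, and P4ha3 rose from 0.483 ± 0.218 to 3.51 ± 1.44 CPM. Col5a1 went from -1.18 to -0.41 with the offset and was not called with the offset and the replicate block (-0.42). Col1a1 (3032 ± 341 and 2303 ± 1060 CPM, log2 fold change -0.40, adjusted p = 0.24) and Col3a1 (4499 ± 352 and 3214 ± 1800 CPM, -0.49, adjusted p = 0.213) did not pass the threshold. In 2 years replicate 3 both were the highest of the 2-year values, at 3853 and 5812 CPM. Without that library Col1a1 was at -0.77 and Col3a1 at -0.94, both called, 14 genes of the list fell and 3 rose, and the list was called lower (median -0.57), as it was with 1 surrogate variable (median -0.446).

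Elastic fibre genes also divided. Of 22 tested, 7 fell and 3 rose (median -0.07, camera adjusted p = 0.57), while without 2 years replicate 3 there were 9 lower and 1 higher, without 12 weeks replicate 2, 3 or 4 or 2 years replicate 4 also 1 higher, and with the length and GC offset 2 lower and 6 higher. Elastin (Eln) fell from 6046 ± 1700 to 3051 ± 933 CPM (1.98-fold, edgeR adjusted p = 0.00813) and Mfap4 fell 2.24-fold, while the fibulin Efemp1 rose from 89.1 ± 17.6 to 180.4 ± 43.7 CPM (2.02-fold). Of 17 proteoglycan and hyaluronan genes 5 rose and 1 fell, or 2 without 2 years replicate 4 (camera adjusted p = 0.286), including Sdc1 (2.78-fold), the hyaluronan receptor Cd44 (2.02-fold) and the hyaluronan synthase Has1 (7.16-fold). Of 23 matrix proteases and inhibitors 9 rose and 1 fell (camera adjusted p = 0.0264; adjusted p = 0.534 with an estimated correlation). Timp1 rose from 30.7 ± 14.9 to 284 ± 126 CPM (9.23-fold) and Mmp3 from 73.4 ± 11.6 to 429 ± 212 CPM (5.84-fold), and Adamts9 fell 2.64-fold. Timp1 went from 3.21 to 2.37 with the offset. The list was not called without 2 years replicate 3 (median 0.25), where 2 fell.

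TGF-beta pathway genes showed no common direction. Of 22 tested, 6 rose and 4 fell, with a median of -0.12, a mean of 0.06 and no call (camera adjusted p = 0.948). Thbs1, which activates latent TGF-beta, rose from 96.3 ± 24.3 to 364 ± 144 CPM (3.78-fold, edgeR adjusted p = 0.000438). The repressor Ski fell 1.52-fold, and Tgfb2 was at 127 ± 17.8 and 122.6 ± 25 CPM (log2 fold change -0.05, SE 0.17, adjusted p = 0.799). With the length and GC offset 7 rose and 0 fell, and Ski was no longer called (-0.21). Of 12 IGF and angiotensin genes 2 rose and 2 fell (camera adjusted p = 0.71). Igfbp4 rose from 1200 ± 156 to 3843 ± 1680 CPM (3.2-fold) and Igfbp3 2.04-fold. The receptor Igf1r fell 1.68-fold, with a long transcript of 11409 nt and a value of 0.06 with the length and GC offset. Of 14 imprinted growth genes 5 fell and 1 rose (5 and 0 when adjusted over the list alone, 4 and 0 with the offset; camera adjusted p = 0.344), with Peg3 down 3.54-fold and Plagl1 down 2.62-fold; 0 rose without any 1 of the libraries other than 2 years replicate 1 and 4, and 2 without 2 years replicate 4. Of 22 focal adhesion and YAP target genes 8 fell and 2 rose (10 and 2 when adjusted over the list alone, 5 and 2 with the offset; camera adjusted p = 0.13), including Itgb3 (1.84-fold), Actn1 (1.59-fold) and Vcl (1.73-fold), which fell; without 2 years replicate 4 the list was called lower (median -0.41, 11 lower), and 1 rose without any 1 of the 8 libraries.

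Cell cycle and senescence genes rose. Of 30 cell cycle genes 20 rose and 1 fell (21 and 1 when adjusted over the list alone), with a median of 0.81 (camera adjusted p = 8.93e-05; adjusted p = 0.531 with an estimated correlation). Mcm5, part of the replicative helicase, rose from 5.39 ± 0.73 to 15.4 ± 2.32 CPM (2.86-fold, edgeR adjusted p = 3.05e-05), Mcm3 2.29-fold, Pcna 1.73-fold and the mitotic kinase Aurkb 4.42-fold. Of the 20 that rose, 17 still did so with the length and GC offset, and Pcna was no longer called with it (0.21). Mki67, a long transcript of 10061 nt, was the member that fell (19.5 ± 7.87 to 7.29 ± 4.81 CPM, log2 fold change -1.42, adjusted p = 0.035). That call was lost with the offset (-0.79) and with the replicate block (-1.55), and without 12 weeks replicate 1 (-1.35), 12 weeks replicate 2 (-1.16), 2 years replicate 1 (-1.26) or 2 years replicate 3 (-1.49). Without 12 weeks replicate 4, 2 members fell. All 16 T and NK cell genes and all 11 B and plasma cell genes tested rose in the same comparison. Bulk counts do not show which cells the cell cycle transcripts came from. Of 20 genes of senescence and secreted factors 14 rose and 1 fell, or 2 without 2 years replicate 4 (median 1.30, camera adjusted p = 0.000105; adjusted p = 0.394 with an estimated correlation). Cdkn2a, a cell cycle inhibitor gene, was low in all libraries and rose from 0.167 ± 0.0643 to 0.907 ± 0.25 CPM (5.25-fold, edgeR adjusted p = 0.000928). Counts per gene do not show which of its transcripts rose. Il1b rose 34.6-fold, Ccl2 20.9-fold and Ccl7 25.3-fold, all of them cytokine genes that macrophages also express. With the offset Cdkn2a, Il1b, Ccl2 and Ccl7 went from 2.39, 5.11, 4.39 and 4.66 to 1.805, 4.46, 3.44 and 3.71.

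Energy metabolism and stress genes gave several list calls. Of 34 oxidative phosphorylation genes 28 rose and 0 fell (30 and 0 when adjusted over the list alone; camera adjusted p = 1.97e-07; adjusted p = 0.531 with an estimated correlation). These transcripts are short (median 1186.5 nt), and with the length and GC offset 2 rose and 8 fell. Ndufb8 rose 1.95-fold and remained called with the offset (0.60), Cox4i1 rose 1.93-fold and was not called with it (0.16), and Ndufa1 rose 1.8-fold and was called lower with it (-0.51). Of 18 glycolysis genes 11 rose and 2 fell (11 and 3 when adjusted over the list alone; camera adjusted p = 0.0264; adjusted p = 0.534 with an estimated correlation), with Ldha up from 180.7 ± 11.5 to 367.9 ± 25.2 CPM (2.04-fold, edgeR adjusted p = 5.29e-05) and Pfkm down 1.81-fold; the list was not called with the offset and the replicate block (median 0.244, adjusted p = 0.0503). Of 19 endoplasmic reticulum stress genes 9 rose and 1 fell (camera adjusted p = 0.016; adjusted p = 0.607 with an estimated correlation), including Sdf2l1 (3.17-fold) and Xbp1 (1.84-fold); with the offset the median went from 0.344 to 0.264 and the list was no longer called (adjusted p = 0.0503, and 0.000941 to 0.607 over its alternatives). Antibody-secreting cells also express Xbp1 and Sdf2l1, and all 11 B and plasma cell genes tested rose in the same comparison (median 3.86). Of 19 immediate early and heat shock genes 5 rose and 0 fell (4 and 0 when adjusted over the list alone; camera adjusted p = 0.158), with Junb up 3.6-fold and Ier3 up 2.73-fold (1.45, and 0.79 with the offset); without 12 weeks replicate 4 the list was called higher (median 0.61), and 3 rose without 12 weeks replicate 2 or 2 years replicate 3 or 4. Of 17 circadian clock genes 3 rose and 5 fell, with a median of 0.24, a mean of -0.12 and no call (camera adjusted p = 0.432); 1 rose without 12 weeks replicate 2, 3 or 4 or 2 years replicate 2. Per3 fell 3.94-fold and Per2 2.71-fold, Bhlhe40 rose 2.59-fold, and Clock fell 1.84-fold but was not called with the offset (-0.19). The time of day of dissection is not given in the sources used here.

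The endothelial, fibroblast, cartilage and nerve lists each had members called in both directions. Of 18 endothelial genes 2 rose and 3 fell (camera adjusted p = 0.648), with Erg down from 78.3 ± 14.7 to 33.8 ± 8.37 CPM (2.32-fold, edgeR adjusted p = 0.000483) and Nos3 down 2.0-fold; without 12 weeks replicate 1, 6 fell, and without 12 weeks replicate 2 or 2 years replicate 2, 1 rose. Of 16 adventitial fibroblast genes 2 rose and 3 fell, or 5 without 2 years replicate 3 (camera adjusted p = 0.894), with Ly6a up 4.11-fold (2.04, and 1.20 with the length and GC offset), Cd34 up 1.92-fold and Gsn down 2.67-fold. Among 16 cartilage and bone genes 8 rose and 3 fell (camera adjusted p = 0.169). Spp1 (osteopontin), also a macrophage product, rose from 7.51 ± 7.46 to 383 ± 145 CPM (51.2-fold, adjusted p = 0.00105; log2 fold change 5.68, 6.50 without 12 weeks replicate 1 and 5.08 with the offset), Comp rose 4.14-fold and Runx2 1.82-fold. Of 13 nerve and Schwann cell genes 3 rose and 2 fell (median -0.04, mean 0.06, camera adjusted p = 0.747), with Mbp up 2.92-fold. Of 10 mesothelial genes 0 passed the threshold (2 rose without 2 years replicate 2 or 4, and 1 fell without replicate 3); camera adjusted p = 0.611. The most abundant, Upk3b, was at 58.9 ± 9.66 and 119 ± 84.3 CPM (log2 fold change 1.01, edgeR adjusted p = 0.0605). Its fold change was 0.39 without 2 years replicate 3. The gene was called higher in 7 of 21 alternatives, among them the fit without 2 years replicate 4 (1.23). The next, Msln, was at 24.93 ± 6.93 and 28.14 ± 21.8 CPM (log2 fold change 0.16, edgeR adjusted p = 0.781), and its fold change was -0.53 without 2 years replicate 3.

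Some fat and striated muscle transcripts, such as Myh6, varied widely between libraries. Plin4, Prdm16 (189.3 ± 17.2 CPM at 12 weeks) and Ryr2 were steady between the 12-week libraries. White adipocyte genes gave 1 higher and 1 lower of 17 (0 and 1 when adjusted over the list alone; camera adjusted p = 0.314), and brown adipocyte genes 1 higher and 2 lower of 12 (camera adjusted p = 0.741). Without 12 weeks replicate 3 these became 8 higher and 1 lower, and 6 higher and 2 lower, and the white adipocyte list was called higher (median 1.13). Without any other 1 library but 2 years replicate 4, 0 white adipocyte genes rose, and without 2 years replicate 3, 2 fell. With the replicate block 6 white adipocyte genes rose and 1 fell, and with limma voom and sample weights 0 rose and 1 fell. Plin4, a lipid droplet protein, fell from 589.8 ± 22 to 202 ± 56.7 CPM (2.92-fold, edgeR adjusted p = 7e-05) and Prdm16 fell 2.84-fold (-1.50, and -0.85 with the length and GC offset). Of 8 cardiac genes 4 fell (camera adjusted p = 0.257) and of 12 skeletal muscle genes 1 fell (0 when adjusted over the list alone; camera adjusted p = 0.373). The heart myosin Myh6 was at 428 CPM in 12 weeks replicate 3 against 6.77 to 19.8 CPM in the other 12-week libraries, and its log2 fold change was -5.18 (adjusted p = 0.0438). That call was lost without 12 weeks replicate 3 (-2.09), without 12 weeks replicate 4 (-5.54), and without 2 years replicate 1 (-6.64), 2 (-5.05), 3 (-4.90) or 4 (-4.84). It was lost in 15 of 21 alternatives, among them DESeq2, limma voom (adjusted p = 0.0863) and the replicate block (edgeR adjusted p = 0.238). With DESeq2, or limma voom with or without sample weights, 1 of 8 cardiac genes fell. Ryr2, a calcium channel of muscle, fell from 163 ± 18.3 to 24.7 ± 8.46 CPM (6.61-fold, adjusted p = 8.95e-06). Its transcript is 16814 nt long, and the log2 fold change went from -2.72 to -1.62 with the offset. Without 12 weeks replicate 3, 2 of 8 cardiac genes fell, without any 1 of the 2-year libraries 1 of 8 to 10 fell, without 12 weeks replicate 1, 6 of 10 fell, and without 12 weeks replicate 2, 6 of 9. Without 12 weeks replicate 2 or 3, or any 1 of the 2-year libraries, 0 skeletal muscle genes fell.

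**Figure D3:**
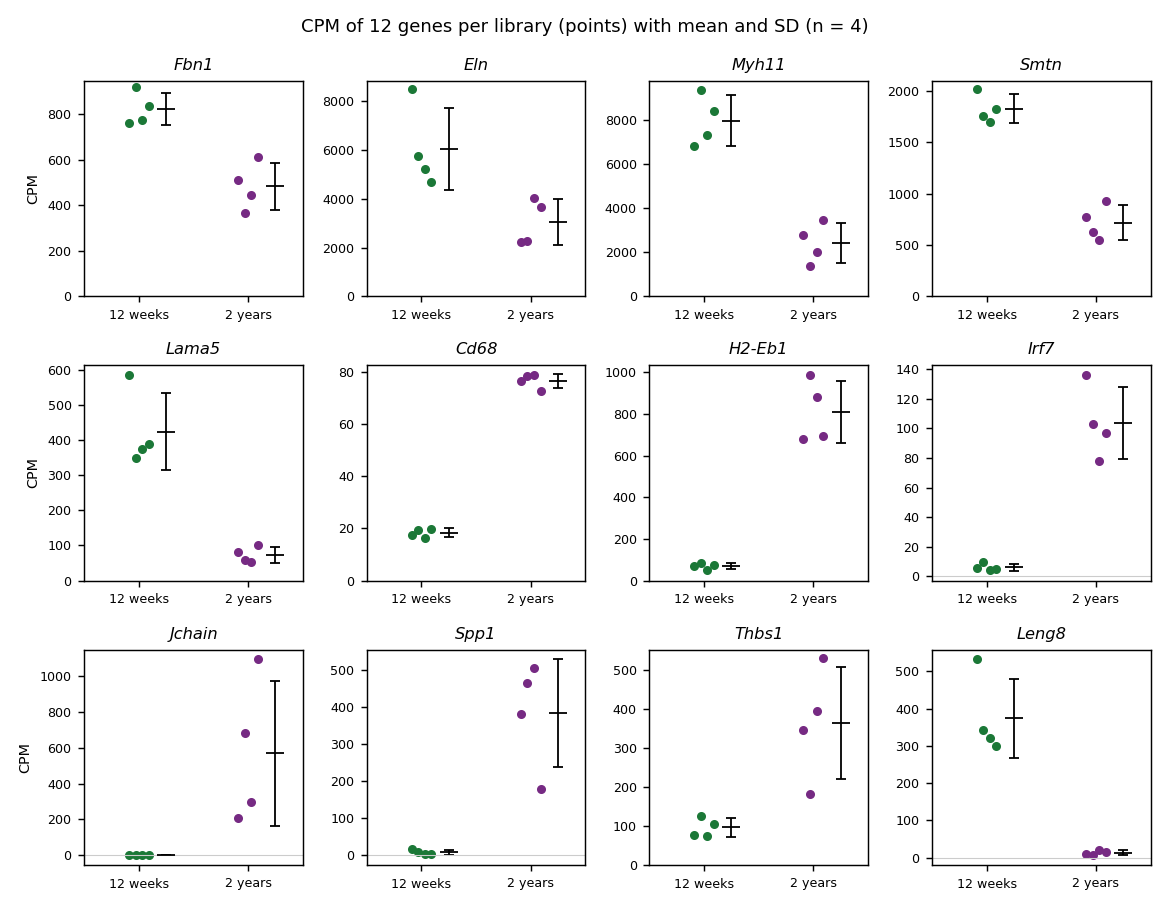
CPM (vertical axes, linear from 0) of 12 genes in each library, with points for the 4 libraries at 12 weeks and the 4 at 2 years and a bar for mean ± SD. The groups do not overlap for these genes; Myh11 falls from a mean of 7962 to 2416 CPM and H2-Eb1 rises from 70.04 to 810.6 CPM.

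The spread between mice, measured as a distance in log2 CPM, did not differ detectably between the ages. The distance of a library from the mean of the other libraries of its group was 0.422 ± 0.0643 at 12 weeks and 0.493 ± 0.0984 at 2 years in log2 units (SD, n = 4; two-sided exact permutation p = 0.314). Each distance was computed within the true groups, so the distances of a group share libraries and are not independent. The permutation p is therefore only approximate for spread. The largest distance, 0.635, belonged to 2 years replicate 3. That library also had the highest mitochondrial share, 10.3% of counts against 4.15 to 5.94% in the other 2-year libraries. The chi-square per degree of freedom between pairs, in contrast, was higher for every 2-year pair than for any 12-week pair. It was 23.5 to 54.1 at 12 weeks and 54.2 to 150.5 at 2 years. Pairs share libraries, and this difference was not tested.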

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

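The tests of the length trend, the immune genes and the nuclear transcripts with unspliced introns were chosen after those patterns were seen, and the test of tissue macrophage genes and that of the nuclear transcripts against the length trend also after the values they measure were seen. Among 272 groups of 4 libraries examined (genes named in the text and library measures), 17 had a single library far from the rest by Dixon's ratio, and about 13.6 would be expected by chance, since chance marks about 1 group in 20.

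At the level of whole libraries, 2 years replicate 3 stood apart in the share of counts in its 20 most counted genes (16.7% against 12.23 to 12.95%) and on the second principal component (54.6 against -23.6 to -11.8). In 2 years replicate 2, haemoglobin took 0.824% of counts against 0.177 to 0.236% in the other 2-year libraries. Among genes at 2 years, replicate 3 was apart for Efemp1 (245.9 CPM), Pfkm (38.69 CPM), Ddx5 (337.9 CPM) and Taf1d (34.98 CPM), replicate 2 for Adamts9 (7.59 CPM), and replicate 4 for Csf3r (6.35 CPM). At 12 weeks, replicate 1 was apart for Npas4 (25.2 CPM), Bmp1 (210.1 CPM) and Bst2 (19.1 CPM), replicate 2 for Ndufa1 (23.7 CPM) and Vcl (1029 CPM), replicate 3 for Acta2 (12190 CPM) and C5ar1 (8.51 CPM), and replicate 4 for Ccl7 (0.324 CPM).

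The number of genes changed with age was set against other divisions of the same 8 libraries. Of the 35 splits into 4 and 4, only the real one (1 split) gave as many as 7272 genes, and the highest of the other splits gave 0. For changes of at least 2-fold, again 1 split, the real one, gave as many as 3127 and the highest other gave 0. Every other split placed libraries of both ages on each side, so the difference between the ages added to the spread within its groups. Counts of 0 were therefore likely in those splits in any case, and the comparison cannot exclude chance. It also does not separate age from other differences between the groups.

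Fold changes fell with transcript length. If incoming immune cells with short transcripts were the cause, the trend should be weak among smooth muscle, matrix, adhesion, endothelial and fibroblast genes, yet across 142 of these the Spearman correlation was -0.444. Reads from introns may contribute, since at a given transcript length the fold change fell with intron length (slope -0.0782 per 10-fold, 95% interval -0.113 to -0.0431). Yet among 350 genes without introns the correlation was still -0.214 (95% interval -0.312 to -0.113), which argues against intronic reads as the whole cause. Both intervals treat genes as independent and leave out variation between mice. A difference in RNA handling or library preparation remains open: the length slopes of the age groups were separated by a gap of 0.233, and because sample numbering follows age it cannot be told apart from a true change with age. Both explanations bear on Fbn1, oxidative phosphorylation and ribosomal protein genes, whose results moved with the offset.

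Immune genes were higher at 2 years in all 5 lists examined (macrophage, T and NK cell, B and plasma cell, interferon response, antigen presentation), and none of these calls held with an estimated correlation (adjusted p = 0.418, 0.394, 0.531, 0.516 and 0.0781). The length trend cannot be the cause of the whole pattern, because 81 of 82 called members, a share of 0.988, were still higher with the length and GC offset. More blood in the tissue, as the red blood cell genes would allow, should not raise genes of resident macrophages that blood leukocytes hardly express; their median log2 fold change was 1.62 (lower quartile 0.78, 6 of 8 called higher), so blood is unlikely as the only source. A lymph node in the dissection should bring more lymphocyte than macrophage transcripts. The rise of 5 lymphocyte genes was at most 0.0571 of the rise of 5 macrophage genes in any 2-year library. Those lymphocyte genes left out Jchain, which rose to 570.2 CPM, and the constant segments listed at 0 could not be used. The ratio therefore cannot decide whether lymph tissue added to the macrophage genes, and lymph tissue remains open. As a hypothesis, macrophages may be more numerous or more active in the aorta at 2 years; counts per cell were not measured.

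A set of transcripts known to be kept in the nucleus with unspliced introns was lower at 2 years. Of 34 such genes, listed without Leng8 and others whose values had been seen, 31 fell and 0 rose, with a median log2 fold change of -1.46. Against 10000 random lists matched on length, GC share and expression, the share with a median as low was 0.01%. That share counts the list itself and is the smallest possible. Random genes need not move together as related genes do, so the share does not measure variation between mice. The median was -1.61 with the length and GC offset, so removing a trend on annotated transcript length did not weaken the fall. The offset does not model reads from introns. It therefore cannot exclude that the length trend and this fall share a source. The result is consistent with more incompletely spliced nuclear RNA in the 12-week libraries, whether from RNA handling, library preparation or the tissue, and also with a true fall of these genes with age; the counts hold no exon and intron separation to decide.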

How the results depend on the processing

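The length and GC offset and the removal of 2 libraries together were chosen after seeing the data; all other settings were planned. No setting moved the numbers of changed genes by more than 1.5 times: leaving out each library gave 3096 to 3620 higher and 3201 to 3801 lower genes, and 1536 to 1771 and 1385 to 1642 by at least 2-fold. The share of higher genes among calls was 49.7% and ranged from 44.8% with the offset and the replicate block (45.4% with the offset) to 56.2% with upper-quartile factors. Leave-one-out fits kept 84.9 to 93.1% of the genes called with all libraries, and the offset kept 72.4% (5266 genes, of which 105 changed direction). Of 117 called genes named in the text, 106 kept call and direction in every alternative run; 7 of 9 uncalled genes were called in some alternative. Of 34 lists, 14 were higher and 2 lower by camera; with an estimated correlation 0 were higher and 0 lower (3 with an unadjusted p under 0.05; the cause was not tested), while fry gave 16 and 3, and leaving out a library 13 to 16 and 2 to 3. The difference in spread between the ages was 0.00819 to 0.149 over leave-one-out fits and its exact permutation p was at least 0.0571.

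Called values turned with the offset, which removes the length trend by construction: Fbn1 to 0.15 (0.14 with the replicate block; adjusted p over all alternatives 2.89e-05 to 0.386), Igf1r to 0.0586 (0.0545 with the block), Ndufa1 to -0.51 (-0.51 with the block), and the oxidative phosphorylation list to a median of 0.003 with a lower direction (0.009 with the block). Values that were not called also changed sign, with the offset (Col1a1 0.14, Tgfb2 0.13, Msln -0.07) and elsewhere: the median of the mesothelial list was -0.008 without 2 years replicate 3, that of the white adipocyte list -0.039 with sample weights and that of the circadian clock list -0.436 without 2 years replicate 2, and the elastic fibre, TGF-beta, brown adipocyte, nerve and imprinted medians changed sign in some alternatives. The replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated at -0.308, -0.116, 0.0511 and 0.0253, and not every library correlated best with its own number. With the replicate block 3112 genes were higher and 3320 lower. Depth limits the statements on genes near the floor, such as Gzmk and Cdkn2a at 12 weeks.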

Other observations

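The 34 transcripts known to be kept in the nucleus with unspliced introns were chosen for testing after Leng8 had been seen. Among them the kinases Clk1 and Clk4 fell, with log2 fold changes of -2.24 and -2.18, as did the glycosyltransferase Ogt (-2.68), Nktr (-2.99), Prpf39 (-2.87) and the helicases Ddx5 (-1.75) and Ddx17 (-1.93), all with an edgeR adjusted p of at most 0.000184. Srsf2 (-0.26), Taf1d (-0.34) and Cdk11b (-0.52) did not pass the threshold. Without 2 years replicate 3, Taf1d (-1.11) and Cdk11b (-0.85) were called lower. With the length and GC offset Srsf2 was called lower (-0.67) and Taf1d was at -1.08, called with the replicate block added (-1.35). Relative to the mean of all libraries, the average of the 34 genes lay between 0.589 and 0.898 log2 units above in the 12-week libraries and below it, at -0.984 to -0.543, in the 2-year libraries.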
